A study of Mus musculus with 6 samples.

How the data were processed

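RNA was measured by sequencing in 6 libraries of FACS-sorted DN1a/b thymus cells from C57BL/6 mice, 2 each from Control, RBPJ uninduced and RBPJ 6 days induced mice. Induction used doxycycline injected at 2 mg/ml and then given at 1 mg/ml in drinking water, per the labels' protocols. The groups and replicate numbers come from the sample titles.

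Each deposited file holds whole-number counts of reads per Ensembl gene for 1 library, 47729 genes in each, with no normalization and no line for unassigned reads. HISAT2, StringTie and HTSeq and the build mm10 are named per the submitters' processing notes, without versions or roles. The strand setting and annotation release are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart, and near-identical copies can share reads. Gene names, types and coordinates were taken from GENCODE M21 on GRCm38, the same build as mm10, in which 47310 of the gene IDs matched.

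Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups (minimum count 10, minimum total count 15), which left 18174. Libraries were scaled by TMM, giving factors from 0.824 to 1.13, and CPM are edgeR cpm values on the scaled totals. All 6 libraries entered 1 quasi-likelihood fit (glmQLFit, glmQLFTest) with a mean per group and 3 residual degrees of freedom, because each group has 2 libraries. The fit assumes that the 3 groups share their spread. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, and the threshold was 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. A fold against a group with no counts is a lower bound against a floor of 3 counts per library, and covers counting error only.

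Before the data were examined, 16 gene lists with 242 entries were fixed from textbook knowledge: Notch targets, T-lineage, B-lineage, stem and progenitor, myeloid, conventional dendritic cell, plasmacytoid dendritic cell, natural killer and innate lymphoid, mast cell and basophil, later thymocyte and mature T cell, erythroid, thymic stromal, cell cycle, interferon response, immediate early and heat shock, and integrated stress response genes. Each was tested by camera in limma 3.58.1, which compares a list with all other genes, with its preset correlation of 0.01 and with an estimated correlation, and by fry. The 48 tests of a kind were adjusted together. No camera call held with the estimated correlation, where the lowest adjusted p was 0.0627. By directional fry no list passed in any comparison (lowest adjusted p = 0.0521). Some lists passed the mixed fry test, in which members may change either way (lowest adjusted p = 0.000213).

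The rule for named genes was also fixed then. It takes Rbpj, every tested Notch target, up to 4 members past the threshold with the smallest p from each other list (up to 2 where none passed), and the 6 highest and 6 lowest fold changes among genes past the threshold with an average log2 CPM of at least 2 and groups that do not overlap. That ranking is by fitted fold change, which depends on an added prior count where a group has no counts, so it does not order the true folds of such genes. Clone-named genes and pseudogenes are left out of it, and up to 3 genes next by p are named where too few passed. Pax5, Ebf1, Rbpj-ps3, Cd8a, Cd8b1, Cd4, Bcl11b, Mcpt4 and Tpsb2 were named after their values were seen.

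The fit was tested on simulated counts drawn from the real means and dispersions of the 18174 genes, with 200 genes changed. For RBPJ uninduced vs Control it recovered 10.3% of 2-fold, 41.5% of 4-fold and 54.7% of 8-fold changes, with 12 false among 69 calls. For induced vs uninduced it recovered 10.3%, 48.3% and 66.1%, with 8 false among 79 calls, and for induced vs Control 9.68%, 49.1% and 67.2%, with 15 false among 89. Most 2-fold changes are therefore missed at this size, and the false calls were above the nominal 5% in each simulation. Overlaps between comparisons that share libraries were set beside 20 simulated draws with no group difference. These draws used the same mean share and dispersion for a gene in all libraries, so they assume an equal spread in the groups.

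Total counts ranged from 5098927 to 12932928 per library. Mitochondrial ribosomal RNA took 16.5% of the counts in RBPJ uninduced replicate 2 and 9.26% to 12.4% in the other libraries. Replicates differed by far more than sampling noise, so no library was counted as a duplicate. Chi-square per degree of freedom was 20.6 in Control, 54.1 in RBPJ uninduced and 16.4 in RBPJ 6 days induced. The assumption of a shared spread is therefore in doubt. The shared value can be too small for comparisons with uninduced libraries and too large for induced vs Control. DESeq2 1.42.0, other size factors, other filters, fits of the 4 compared libraries, the replicate number as a block and leaving out each library were the alternatives. List members counted without a library are those past the threshold over all genes tested in that fit, not over the list alone. A fit of protein-coding nuclear genes alone was added after the data had been seen.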

Results

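RNA of sorted mouse thymus cells was sequenced in 3 groups of 2 libraries each. The cells were DN1a/b thymocytes, an early stage of thymocyte development in which cells are not yet committed to the T lineage. Control mice kept RBPJ, the DNA-binding protein through which Notch receptors switch on their target genes. RBPJ uninduced mice lacked it per the labels, and in the third group its expression had been switched on with doxycycline for 6 days. The libraries held between 5098927 and 12932928 counts assigned to genes. Control replicate 2 had 5311391 counts and RBPJ uninduced replicate 1 had 5098927, about the same low depth, and the other 4 libraries had at least 10918205. No label says whether the 2 libraries of a group came from separate mice, so the p-values measure the spread between these libraries, which can be partly technical. Whether Control or uninduced mice received doxycycline is not given in the sources used here. Effects of RBPJ and of doxycycline therefore cannot be told apart in comparisons with the induced libraries, the interferon response genes included.

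Rbpj itself (ENSMUSG00000039191, mm10 chromosome 5, 53466152 to 53657362, plus strand) followed the group labels. Its level was 73.5 ± 0.854 CPM in Control, 29.1 ± 1.28 CPM in RBPJ uninduced and 200.6 ± 3.37 CPM after 6 days of induction (mean ± SD, n = 2 each). It was lower in uninduced than in Control libraries by a log2 fold change of -1.34 (SE 0.186, adjusted p = 0.00495). It was higher after induction than in uninduced libraries by 2.78 (SE 0.193, adjusted p = 0.000507), and higher after induction than in Control by 1.45 (SE 0.182, adjusted p = 0.0175). The labels do not say which part of the gene was removed, so the counts left in the uninduced libraries do not show how much intact transcript remained. Rbpj has a near-identical copy with which it can share reads: the processed pseudogene Rbpj-ps3 (chromosome 6, 46529354 to 46530794) matches the Rbpj transcript over 1441 bases with 4 mismatches, and it held 778 and 815 counts in the induced libraries against 4 to 31 in the others, and gene counts do not show which of these reads came from Rbpj. The first difference was not past the threshold when only the 4 libraries compared entered the fit (-1.36, adjusted p = 0.057), and the difference between induced and Control libraries was not past it without Control replicate 1 (adjusted p = 0.0848), Control replicate 2 (adjusted p = 0.09) or induced replicate 2 (adjusted p = 0.0518).

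**Figure D1:**
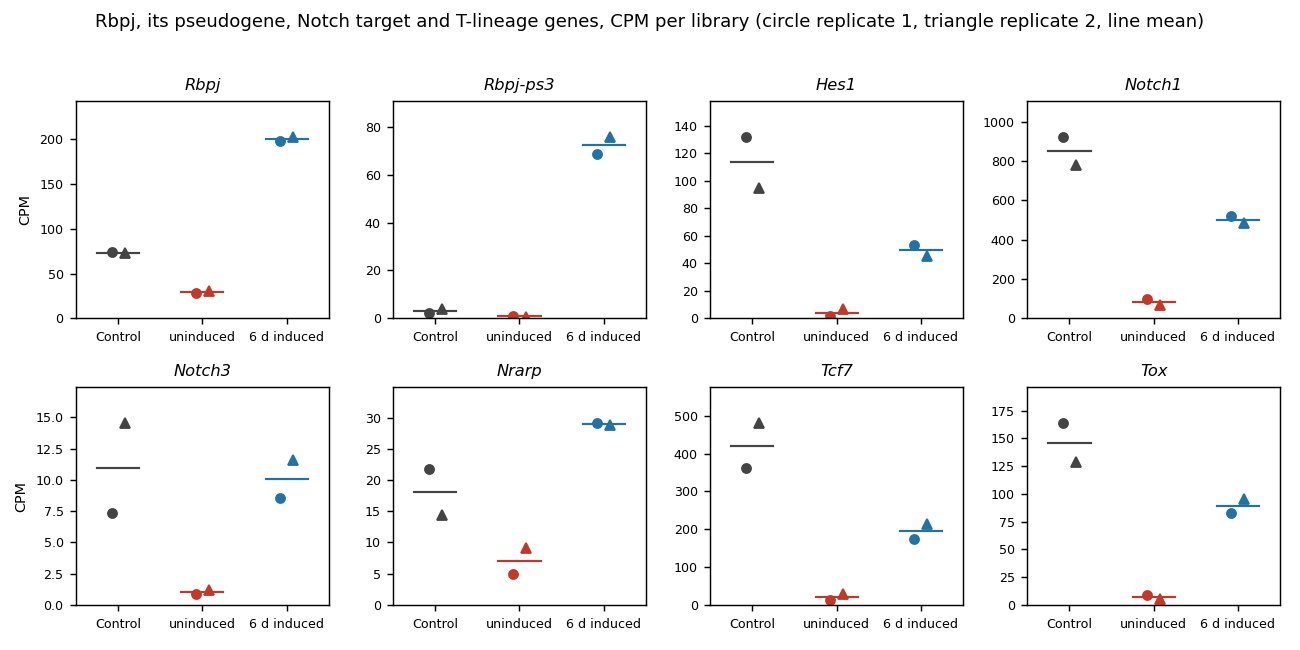
Level of 8 genes in each library, in CPM on a linear axis from 0 for Control, RBPJ uninduced and RBPJ 6 days induced; circles are replicate 1, triangles replicate 2 and lines the mean of the 2. Hes1 stood at 132 and 94.99 CPM in Control, 1.39 and 6.80 CPM in uninduced and 53.1 and 45.6 CPM in induced libraries.

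The comparison of RBPJ uninduced with Control asked which transcripts of DN1a/b cells differ when RBPJ is missing. Of 18174 genes tested, 452 were higher and 533 were lower in the uninduced libraries. The Notch target Hes1, a transcriptional repressor, fell from 114 ± 26.1 to 4.10 ± 3.82 CPM, and Notch1, the receptor that starts T-cell development, fell from 853 ± 100.4 to 83.2 ± 20.5 CPM. Tcf7, which encodes the early T-lineage factor TCF1, fell from 420.1 ± 84.1 to 20.2 ± 10.2 CPM. Of 8 mast cell and basophil genes 7 rose (camera adjusted p = 0.0627 with an estimated correlation), among them Gata2, a factor of progenitors and mast cells, from 13.1 ± 5.49 to 236 ± 65.8 CPM (all mean ± SD, n = 2 per group).

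Among the Notch targets, 11 of 12 listed genes could be tested, and 3 fell and none rose, with 4 lower when adjusted over the list alone. They were Hes1 (log2 fold change -4.71, SE 0.528, adjusted p = 0.00196), Notch1 (-3.36, SE 0.219, adjusted p = 0.000186) and Notch3 (-3.34, SE 0.620, adjusted p = 0.0171), the last not past the threshold without Control replicate 2. Nrarp, a feedback inhibitor of Notch signalling, was at -1.37 (adjusted p = 0.091). Dtx1 was at -1.67 (adjusted p = 0.443), Hey1 at -2.38 (adjusted p = 0.35), Il2ra at -0.92 (adjusted p = 0.713) and Myc at 0.49 (adjusted p = 0.348). The uninduced libraries disagreed on Dtx1 and Il2ra. Dtx1 stood at 21.9 and 20.3 CPM in Control and at 0 and 12.7 CPM in uninduced replicates 1 and 2. Il2ra stood at 30.2 and 15.9 CPM in Control and at 0.522 and 23.5 CPM in those uninduced libraries. Their missing calls therefore do not show that these genes were unaffected. Hes5 was at 0.07 (adjusted p = 0.994), Hey2 at 0.33 (adjusted p = 0.976) and Heyl at 0.83 (adjusted p = 0.929), with averages of no more than 2.12 CPM in any group. The list ranked low among all genes by camera with its preset correlation (adjusted p = 5.99e-07), but not past the threshold with an estimated one (adjusted p = 0.168 with an estimated correlation).

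Of 22 tested T-lineage genes, 6 fell and none rose, and 13 were lower when adjusted over the list alone. Tox, a factor of T-cell development, changed by -4.37 (adjusted p = 0.000273), Tcf7 by -4.36 (adjusted p = 0.000387) and the signalling kinase Lck by -3.96 (adjusted p = 0.00173). Cd6 stood at 19.7 and 34.9 CPM in Control and at 0.174 and 0.223 CPM in uninduced libraries. The list ranked low (camera adjusted p = 1.07e-15, and adjusted p = 0.198 with an estimated correlation). Of 15 later thymocyte and mature T cell genes, 6 fell and none rose, and 10 were lower and 1 higher when adjusted over the list alone (camera adjusted p = 2.77e-13, and adjusted p = 0.0627 with an estimated correlation). The T-cell receptor beta constant genes Trbc1 and Trbc2, near-identical copies whose reads cannot be cleanly divided, changed by -6.16 (SE 0.341) and -5.91 (SE 0.319), both with an adjusted p of 6.33e-05. Tcrg-C1 changed by -2.76 (adjusted p = 0.0141), not past the threshold without Control replicate 1. Control replicate 2 stood apart in genes of both lists, none of them past the threshold: Cd8a was at 79.96 CPM there and at 3.20 CPM in replicate 1, Cd8b1 at 56.2 and 3.58 CPM, Cd4 at 61.6 and 5.41 CPM and Bcl11b at 131 and 5.10 CPM. The median log2 fold change of the T-lineage list was -2.50 and that of the later thymocyte and mature T cell list -2.76, and without Control replicate 2 they were -0.84 and -1.51, with 5 lower members in each. Without Control replicate 1, uninduced replicate 1 or 2, or induced replicate 1 or 2, the T-lineage list had 12, 11, 14, 10 and 11 lower members, and the later list had 5, 9, 10, 9 and 10.

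Of 8 tested mast cell and basophil genes, 7 rose and none fell, and 8 were higher when adjusted over the list alone. Gata2 changed by 4.21 (SE 0.330, adjusted p = 0.000387), the histamine-synthesising enzyme Hdc by 2.87 (SE 0.285, adjusted p = 0.0012) and the mast cell chymase Cma1 by 7.14 (SE 1.14, adjusted p = 0.00887). Ms4a2, a chain of the IgE receptor, stood at 0.0761 and 0.354 CPM in Control and at 30.8 and 14.4 CPM in uninduced libraries (adjusted p = 0.00193). The list ranked high (camera adjusted p = 1.08e-20, and adjusted p = 0.0627 with an estimated correlation). It had 4 higher members without Control replicate 2.

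Of 17 myeloid genes, 8 rose and none fell, and 10 were higher when adjusted over the list alone. Mpo, the granule enzyme myeloperoxidase, rose from 458 ± 52.4 to 3215 ± 703 CPM (2.81, SE 0.335, adjusted p = 0.00249). The granule proteases Ctsg and Prtn3 changed by 3.87 (adjusted p = 0.00398) and 4.70 (adjusted p = 0.00403), and the myeloid factor Cebpa stood at 1.75 and 1.42 CPM in Control and at 24.5 and 27.5 CPM in uninduced libraries (adjusted p = 0.00365). The list ranked high (camera adjusted p = 1.53e-14, and adjusted p = 0.168 with an estimated correlation). Of 8 erythroid genes, 2 rose and none fell, among them Klf1, the master factor of red cell genes (6.23, SE 0.839, adjusted p = 0.00424). The hemoglobin genes did not pass, and 2 members were higher adjusted over the list alone (camera adjusted p = 0.00733, and adjusted p = 0.461 with an estimated correlation). That camera call was also lost without Control replicate 1 or uninduced replicate 2.

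Stem and progenitor genes went both ways, with 4 of 18 higher and 1 lower, and 6 higher and 4 lower when adjusted over the list alone. Gata2 belongs to this list too. Lmo2 and Tal1, partners in the blood stem cell transcription complex, changed by 2.14 and 2.61 (both adjusted p = 0.00133), and Mycn by -2.67 (adjusted p = 0.00405). The median of the list was -0.41 while camera placed it upward without passing (adjusted p = 0.191). B-lineage genes depended on 1 library. Cd79a alone of 17 tested members passed (5.49, SE 1.31, adjusted p = 0.0435), and 12 were higher when adjusted over the list alone (camera adjusted p = 0.000284, and adjusted p = 0.522 with an estimated correlation). RBPJ uninduced replicate 2 held 249 CPM of Pax5 and 162 CPM of Ebf1, and replicate 1 held 5.39 CPM of each. Without replicate 2 the list pointed downward and did not pass (adjusted p = 0.735). The call of Cd79a was lost there too, and also without Control replicate 1, without Control replicate 2 and with the 4 compared libraries alone.

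Cell cycle genes were higher in the uninduced libraries by a small amount, with a median log2 fold change of 0.86 and all 24 fold changes above 0. By test 9 rose and none fell, and 19 were higher when adjusted over the list alone. Mki67, a marker of dividing cells, changed by 0.96 (SE 0.183, adjusted p = 0.0196), the replication licensing gene Mcm2 by 0.86 (adjusted p = 0.0273), Rrm2 by 1.19 (adjusted p = 0.0289) and Ccne1 by 2.63 (adjusted p = 0.0348). The list ranked high (camera adjusted p = 1.5e-11, and adjusted p = 0.198 with an estimated correlation). Without Control replicate 1, or without Control replicate 2, no member passed in edgeR, while 20 had an unadjusted p under 0.05 and 12 passed in DESeq2 with all 6 libraries.

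In the remaining lists few members passed. Irf8 (2.03, adjusted p = 0.0106) was the member of 12 conventional dendritic cell genes that rose, with 2 higher adjusted over the list alone, and the chemokine receptor Ccr9 (-4.09, adjusted p = 0.00422) the member of 11 plasmacytoid dendritic cell genes that fell, with 2 higher and 3 lower adjusted over the list alone. Of 18 natural killer and innate lymphoid genes, the interleukin 33 receptor Il1rl1 (5.55, adjusted p = 0.000568) and Zbtb16 (2.29, adjusted p = 0.0424) rose and Il18r1 (-2.04, adjusted p = 0.0293) fell, the same 2 and 1 as adjusted over the list alone. Pecam1 (-0.80, adjusted p = 0.0348) fell among 12 thymic stromal genes, 1 lower adjusted over the list alone. Camera placed these 4 lists past no threshold (adjusted p = 0.25, 0.19, 0.207 and 0.576). Of 12 immediate early and heat shock genes, Nr4a1 (-3.82, adjusted p = 0.0129), Zfp36 (-0.91, adjusted p = 0.0321) and Egr1 (-0.85, adjusted p = 0.0433) fell, with 1 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.0427, and adjusted p = 0.437 with an estimated correlation). Asns (3.59, adjusted p = 0.0263) rose among 11 integrated stress response genes, 3 of them higher adjusted over the list alone (camera adjusted p = 0.103). No interferon response gene of 13 passed in edgeR, over all genes or adjusted over the list alone, 2 had an unadjusted p under 0.05 and DESeq2 called 0 (camera adjusted p = 0.737). Of the calls in this group, those of Asns, Zfp36, Egr1 and Pecam1 were lost without either Control library, those of Il18r1 and the immediate early and heat shock list without Control replicate 1, and those of Irf8 and Zbtb16 without Control replicate 2. Leaving out uninduced replicate 2 ended the calls of Asns and Zfp36, uninduced replicate 1 that of Egr1, and induced replicate 1 those of Egr1, Zfp36, Pecam1 and the immediate early and heat shock list.

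Among genes that met the naming rule, those ranked highest by fitted fold change included Car1, a carbonic anhydrase of red cell precursors (9.81, SE 0.780, adjusted p = 0.000387), and Rhd, Aldh1a1 and Zg16, all 3 with no counts in Control. Taking 3 counts per library as the floor, Rhd was at least 55.4-fold, Aldh1a1 at least 35.2-fold and Zg16 at least 25.2-fold higher. Rhd stood at 4.35 and 37.7 CPM in the uninduced libraries and Aldh1a1 at 5.56 and 21.2 CPM. Their bounds were 11.45-fold and 14.7-fold without uninduced replicate 2, 99.2-fold and 55.8-fold without uninduced replicate 1. They were 91.97-fold and 58.5-fold without Control replicate 2, where that of Zg16 was 41.9-fold. Those ranked lowest included Sema3d, at least 52.5-fold lower, Fasl, which encodes the death receptor ligand, at least 48.9-fold lower, and gene segments of the T-cell receptor beta locus on chromosome 6. Trbj1-4 was at least 38.0-fold, Trbd1 at least 35.2-fold and Trbj2-1 at least 22.4-fold lower, the last 2 at least 23.1-fold and 14.9-fold without Control replicate 1. Trbj1-5 stood at 12.3 ± 2.92 CPM in Control with 0.0557 ± 0.0788 CPM in uninduced libraries. Leaving out Control replicate 1 gave 185 higher and 260 lower genes, Control replicate 2 gave 198 and 339, uninduced replicate 1 gave 1007 and 993, and uninduced replicate 2 gave 626 and 1165. DESeq2 called 719 and 942, no low-count filter gave 725 and 815, and a fit of the 4 compared libraries alone gave 93 and 126.

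**Figure D2:**
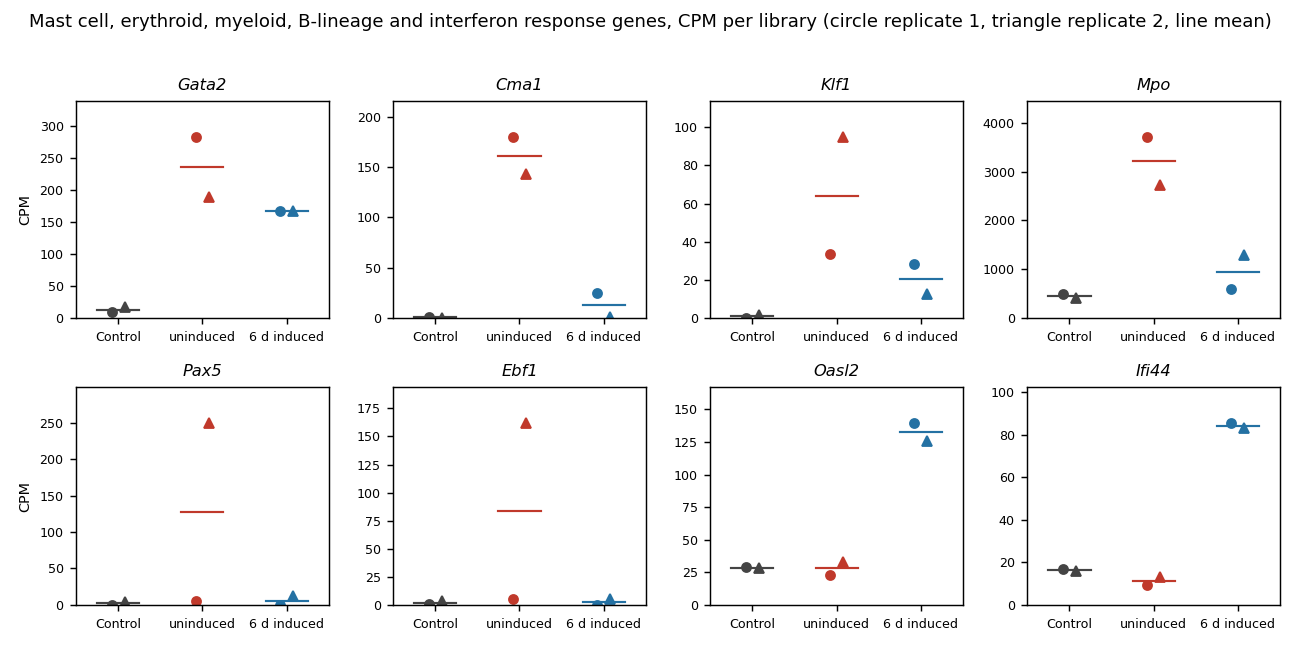
Level of 8 genes in each library, in CPM on a linear axis from 0, for Control, RBPJ uninduced and RBPJ 6 days induced; circles are replicate 1, triangles replicate 2 and lines the mean of the 2. Mean Gata2 was 13.1 CPM in Control, 236 CPM in uninduced and 167 CPM in induced libraries, while Pax5 reached 249 CPM in uninduced replicate 2 and at most 11.6 CPM elsewhere.

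The comparison of RBPJ 6 days induced with RBPJ uninduced asked what changed once RBPJ was expressed again. In the induced libraries 282 genes were higher and 75 were lower. Hes1 rose from 4.10 ± 3.82 to 49.3 ± 5.31 CPM, Notch1 from 83.2 ± 20.5 to 502 ± 25.6 CPM and Tcf7 from 20.2 ± 10.2 to 194 ± 26.5 CPM. Of 13 interferon response genes 4 rose (camera adjusted p = 0.168 with an estimated correlation), and Mpo fell from 3215 ± 703 to 952 ± 493 CPM (mean ± SD, n = 2 per group).

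Of the 11 Notch targets tested, 4 rose and none fell, also 4 when adjusted over the list alone. They were Hes1 (3.50, SE 0.509, adjusted p = 0.0124), Notch1 (2.59, SE 0.213, adjusted p = 0.000951), Notch3 (3.23, adjusted p = 0.035) and Nrarp (2.04, adjusted p = 0.0407), the last 2 not past the threshold without either induced library (camera adjusted p = 2.1e-07, and adjusted p = 0.168 with an estimated correlation). Dtx1 was at 2.52 (adjusted p = 0.28), Hey1 at 2.70 (adjusted p = 0.341), Il2ra at 1.45 (adjusted p = 0.528) and Myc at -0.24 (adjusted p = 0.718). The uninduced libraries disagreed on Dtx1 and Il2ra here too, so these missing calls do not show that the genes were unaffected. Hes5 was at -3.70 (adjusted p = 0.487), Heyl at -1.85 (adjusted p = 0.781) and Hey2 at -0.24 (adjusted p = 0.977), so 7 of the 11 fold changes were above 0. Of the 22 T-lineage genes 5 rose, 6 adjusted over the list alone, among them Tox (3.66, adjusted p = 0.000951), Tcf7 (3.24, adjusted p = 0.00305), Lck (3.52, adjusted p = 0.00557) and Cd6, at 8.83 and 7.64 CPM after 0.174 and 0.223 CPM (adjusted p = 0.00517), with camera at adjusted p = 2.55e-10 (adjusted p = 0.279 with an estimated correlation). Of the 15 later thymocyte and mature T cell genes 5 rose, 6 adjusted over the list alone (camera adjusted p = 1.14e-12, and adjusted p = 0.0627 with an estimated correlation). Trbc1 and Trbc2 changed by 4.67 and 4.64 (both adjusted p = 0.000507) and Tcrg-C1 by 3.44 (adjusted p = 0.0123). With the 4 compared libraries alone, Hes1 (adjusted p = 0.0837), Lck (adjusted p = 0.0563), Cd6 (adjusted p = 0.0719) and Tcrg-C1 (adjusted p = 0.0663) were not past the threshold. Notch3 and Nrarp were not past it there either, while Notch1, Tox, Tcf7, Trbc1 and Trbc2 were.

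Interferon response genes had all 13 fold changes above 0, 4 rose, and 10 were higher adjusted over the list alone. Ifi44 changed by 2.88 (SE 0.275, adjusted p = 0.00234), Oasl2 by 2.23 (SE 0.241, adjusted p = 0.00362), Ifit1 by 2.36 (SE 0.316, adjusted p = 0.00801) and Rtp4 by 2.35 (SE 0.324, adjusted p = 0.00928). The list ranked high (camera adjusted p = 8.37e-16, and adjusted p = 0.168 with an estimated correlation). All 24 cell cycle genes had fold changes below 0, with a median of -0.79, and 3 fell: Rrm2 (-1.63, adjusted p = 0.0161), Mcm2 (-1.04, adjusted p = 0.0259) and Mcm5 (-1.01, adjusted p = 0.0369), with 18 lower adjusted over the list alone (camera adjusted p = 8.82e-15, and adjusted p = 0.168 with an estimated correlation). None of the 3 passed without either induced library.

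Mpo alone of 17 myeloid genes fell (-1.76, SE 0.322, adjusted p = 0.0307), with 1 higher and 5 lower adjusted over the list alone, and Hdc alone of 8 mast cell and basophil genes (-1.83, SE 0.270, adjusted p = 0.0134), with 2 lower adjusted over the list alone. Neither call held without induced replicate 1. Camera placed both lists downward (adjusted p = 7.01e-05 and 9.37e-07, with adjusted p = 0.318 and 0.144 with an estimated correlation). Mycn rose by 3.03 (adjusted p = 0.00517) as 1 of 18 stem and progenitor genes, of which 4 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0135, and adjusted p = 0.44 with an estimated correlation). Il18r1 rose by 3.02 (adjusted p = 0.0129) as 1 of 18 natural killer and innate lymphoid genes, 2 adjusted over the list alone (camera adjusted p = 0.14). Shmt2, an enzyme of one-carbon metabolism, fell by 1.15 on the log2 scale (adjusted p = 0.0357) among 11 integrated stress response genes, 4 of them lower adjusted over the list alone (camera adjusted p = 0.00252, and adjusted p = 0.278 with an estimated correlation). Shmt2 was not past the threshold without either induced library, the camera calls of the stem and progenitor and the stress response lists were lost without uninduced replicate 2, and that of the stem and progenitor list also without Control replicate 1.

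In 6 lists no member of 72 tested passed in edgeR, 9 were higher and 16 lower at an unadjusted p under 0.05, and DESeq2 called 5 higher and 4 lower. They were the B-lineage list (camera adjusted p = 3.06e-05 downward, adjusted p = 0.483 with an estimated correlation, upward and not past the threshold without uninduced replicate 2), the erythroid list (camera adjusted p = 0.0147 downward, adjusted p = 0.483 with an estimated correlation, lost without uninduced replicate 2), and the conventional dendritic, plasmacytoid dendritic, thymic stromal, and immediate early and heat shock lists (camera adjusted p = 0.839, 0.142, 0.819 and 0.053). The conventional dendritic list had a median of -0.59 against an upward camera direction, and ranked low without uninduced replicate 1 (adjusted p = 0.000592) and high without uninduced replicate 2 (adjusted p = 7.4e-05). Gata2 fell short of a call here (adjusted p = 0.454), as did Klf1 (-1.65, adjusted p = 0.229).

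Among genes that met the naming rule, those ranked highest by fitted fold change included Sema3d and Fasl, at least 53.95-fold and at least 32.4-fold higher, and the receptor segments Trbj1-4, Trbd1 and Trbj2-1, at least 13.6-fold, 12.9-fold and 9.49-fold, all with no counts in uninduced libraries. The bound of Trbj1-4 was 8.46-fold without induced replicate 2. Trbj1-5 stood at 7.28 ± 3.93 CPM. Those ranked lowest included Papss2 (-3.68), Epdr1 (-2.53), Cnr2, a cannabinoid receptor (-1.90), Nefh (-1.85) and the cyclin Ccnd1 (-1.83), with adjusted p between 0.0189 and 0.0424, each lost without at least 1 induced library. Leaving out induced replicate 1 gave 156 higher and 15 lower genes, induced replicate 2 gave 198 and 16, uninduced replicate 1 gave 825 and 549, and uninduced replicate 2 gave 951 and 234. DESeq2 called 662 and 379, no low-count filter gave 675 and 314, and the 4 compared libraries alone gave 70 and 1.

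All 533 genes lower in uninduced than in Control libraries had fold changes above 0 on induction, and 236 of them (44.3%) were called higher. Of the 452 higher genes, 435 had fold changes below 0 on induction and 61 (13.5%) were called lower. Independent lists of those sizes would share 8.27 and 1.87 genes. Both comparisons use the uninduced libraries, which makes their fold changes run opposite ways by chance, and 20 simulated sets with no group difference gave on average 0.25 (at most 2) and 0 such genes. Those sets gave on average 1.4 and 1.6 calls in the 2 comparisons, so they could hold hardly any shared genes and are no yardstick for lists of these sizes. Across genes, the covariance of the log2 fold changes was -1.92 against a simulated -0.67, and their correlation was -0.69 against -0.51. The simulation gave all libraries the same spread for a gene. Between the real uninduced replicates, which both comparisons share, chi-square per degree of freedom was 54.1. It was 20.6 in Control and 16.4 in induced libraries. The simulated covariance and correlation can therefore be too weak as a yardstick. With 2 uninduced libraries the shared group cannot be split into 2 parts of 2, so part of the overlap and of the covariance can come from the shared libraries. The 533 lower genes had a median log2 fold change of -1.77 in uninduced libraries and -0.30 in induced libraries, both against Control, and the 452 higher genes had 1.48 and 0.71. The genes were chosen by their calls in uninduced vs Control, which by itself makes the first median of each pair larger in size. The medians therefore do not measure how far levels returned. The counts of 236 and 61 became 647 and 453 without uninduced replicate 1, 768 and 161 without uninduced replicate 2, 137 and 13 without induced replicate 1, 176 and 16 without induced replicate 2, and 214 and 25 without Control replicate 2. DESeq2 gave 533 and 271, and no low-count filter gave 514 and 252.

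**Figure D3:**
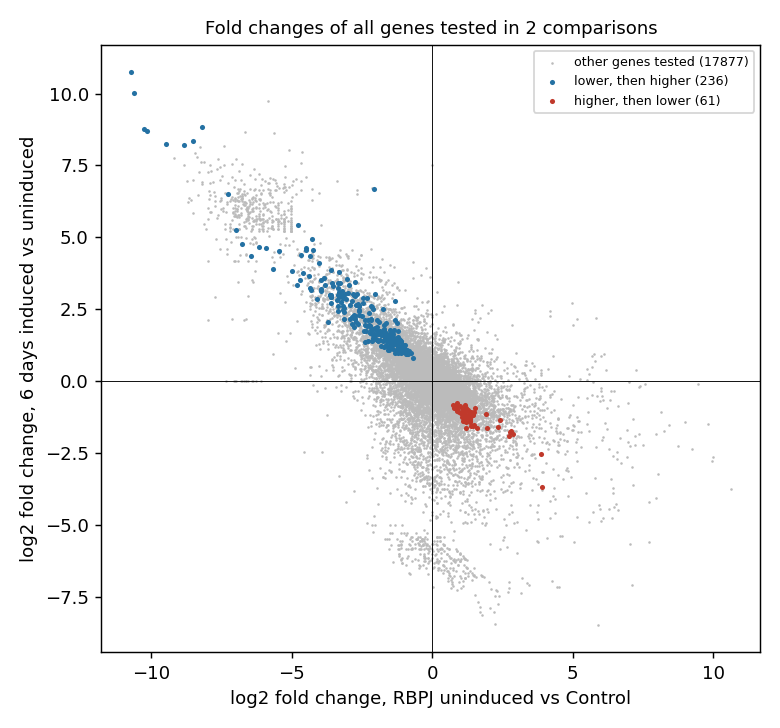
Log2 fold changes of the 18174 genes tested, RBPJ uninduced vs Control on the x axis and RBPJ 6 days induced vs RBPJ uninduced on the y axis, with genes past the threshold in both comparisons with opposite signs in colour. The 236 genes lower and then higher lie at the upper left and the 61 higher and then lower at the lower right; fold changes of genes with no counts in a group depend on the fitted prior count.

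The comparison of RBPJ 6 days induced with Control asked what still differed after induction. Induced libraries had 34 genes higher than Control. Gata2 stood at 167 ± 0.162 CPM against 13.1 ± 5.49 CPM in Control, Il1rl1 at 34.9 ± 13.3 against 1.73 ± 1.05 CPM, and the interferon response gene Oasl2 at 133 ± 9.34 against 28.6 ± 0.446 CPM (mean ± SD, n = 2). In edgeR 0 genes were lower, while 281 were lower at an unadjusted p under 0.05 and DESeq2 called 48 lower and 164 higher.

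Interferon response genes were higher in induced libraries in all 13 members by sign. Of these, 3 rose, and 13 were higher adjusted over the list alone. Oasl2 changed by 2.21 (SE 0.241, adjusted p = 0.00915), Ifi44 by 2.34 (SE 0.267, adjusted p = 0.0106) and Ifit1 by 2.14 (SE 0.311, adjusted p = 0.0338). Ifi44 was not past the threshold without Control replicate 2, and Ifit1 without any 1 of the Control or induced libraries. The list ranked high (camera adjusted p = 9.73e-36, and adjusted p = 0.0965 with an estimated correlation).

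Of the 8 mast cell and basophil genes 2 rose, Gata2 (3.71, SE 0.324, adjusted p = 0.00309) and Ms4a2, which stood at 10.4 and 16.0 CPM after induction against 0.0761 and 0.354 CPM (adjusted p = 0.0175), and 7 were higher adjusted over the list alone (camera adjusted p = 7.61e-22, and adjusted p = 0.0627 with an estimated correlation). Induced replicate 1 stood apart in 3 members not past the threshold over all genes: Cma1 was at 24.8 CPM there and at 1.58 CPM in replicate 2, Mcpt4 at 35.1 and 2.05 CPM and Tpsb2 at 20.2 and 0.652 CPM, with at most 1.68 CPM in Control. Without induced replicate 1 the median log2 fold change of the list was 0.84, against 3.62 with all libraries, and 2 members were higher. Without induced replicate 2, uninduced replicate 1 or uninduced replicate 2, 5, 5 and 4 were higher. Without Control replicate 1, 1 was. Gata2 and Lmo2 (1.54, adjusted p = 0.0288) rose among 18 stem and progenitor genes, 5 adjusted over the list alone (camera adjusted p = 8.46e-11, and adjusted p = 0.168 with an estimated correlation). Il1rl1 (4.47, SE 0.469, adjusted p = 0.00741) rose among 18 natural killer and innate lymphoid genes, 3 adjusted over the list alone (camera adjusted p = 1.12e-06, and adjusted p = 0.244 with an estimated correlation). Beside Ms4a2, genes that met the naming rule and ranked highest by fitted fold change included Zg16, at least 23.4-fold higher (38.9-fold without Control replicate 2), Car1 (8.32, SE 0.776, adjusted p = 0.00442), Samd14 (5.65, adjusted p = 0.0211) and Mfsd2b, a lipid transporter of red cells and platelets, from 1.94 ± 0.263 to 89.0 ± 4.39 CPM (5.54, SE 0.271, adjusted p = 7.88e-05).

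In the other 12 lists no member of 172 tested passed in edgeR, 13 were higher and 15 lower at an unadjusted p under 0.05, and DESeq2 called 8 higher and 6 lower. Notch targets had a median of 0.10 with camera placing them downward (adjusted p = 0.323), Hes1 at -1.20 (adjusted p = 0.741) and Notch1 at -0.77 (adjusted p = 0.313), and 1 was lower adjusted over the list alone. Of the other 9, all with an adjusted p of 1, Nrarp was at 0.67, Dtx1 at 0.85, Hey1 at 0.32, Hey2 at 0.10, Il2ra at 0.54, Myc at 0.24, Notch3 at -0.11, Heyl at -1.02 and Hes5 at -3.63. T-lineage genes ranked low (camera adjusted p = 4.32e-07, and adjusted p = 0.377 with an estimated correlation), with Tcf7 at -1.11 (adjusted p = 0.342), Cd6 at -1.72 (adjusted p = 0.263) and 2 lower adjusted over the list alone, a camera call lost without Control replicate 2. Later thymocyte and mature T cell genes ranked low (camera adjusted p = 0.0147, and adjusted p = 0.305 with an estimated correlation), with Trbc1 at -1.49 (adjusted p = 0.0666) and 4 lower adjusted over the list alone, a camera call lost without any 1 of the 6 libraries. Myeloid genes ranked high (camera adjusted p = 3.4e-15, and adjusted p = 0.168 with an estimated correlation), with Cebpa at 3.26 (adjusted p = 0.0516) and 8 higher adjusted over the list alone. Conventional dendritic cell genes ranked high (camera adjusted p = 0.0156, and adjusted p = 0.504 with an estimated correlation), with Irf8 at 1.94 (adjusted p = 0.0653), a camera call lost without Control replicate 1. Erythroid genes had a median of -1.30 against an upward camera direction (adjusted p = 0.176), with Klf1 at 4.58 (adjusted p = 0.0722) and 2 higher adjusted over the list alone. The B-lineage, plasmacytoid dendritic, thymic stromal, cell cycle, immediate early and heat shock, and integrated stress response lists had camera adjusted p of 0.737, 0.823, 0.207, 0.969, 0.495 and 0.15.

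The lower genes nearest to the threshold were Cnn3 (-1.63, adjusted p = 0.0616), Plekha7 (-1.16, adjusted p = 0.0647) and Trbc1. The calls of Ms4a2, Samd14 and Zg16 were lost without Control replicate 1, and that of Lmo2 without either Control library and with DESeq2-type size factors in edgeR. Leaving out Control replicate 1 gave 20 higher and 10 lower genes, uninduced replicate 1 gave 266 and 71, uninduced replicate 2 gave 244 and 64, induced replicate 1 gave 79 and 1, and induced replicate 2 gave 62 and 1. No low-count filter gave 247 and 57, a fit of the 4 compared libraries alone gave 142 and 35, and protein-coding nuclear genes alone, a choice made after seeing the data, gave 53 and 2.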

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

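Protein-coding nuclear genes alone were chosen as an alternative after seeing the data. Rbpj kept its direction under every alternative run, and lost its call in uninduced vs Control with the 4 compared libraries alone (-1.359) and in induced vs Control without Control replicate 1, Control replicate 2 or induced replicate 2. Counts of calls moved, with higher and lower genes given in that order. In uninduced vs Control (452 and 533) DESeq2 gave 719 and 942, no low-count filter 725 and 815, and the 4 compared libraries 93 and 126. In induced vs uninduced (282 and 75) these gave 662 and 379, 675 and 314, and 70 and 1. In induced vs Control (34 and 0) they gave 164 and 48, 247 and 57, and 142 and 35, and protein-coding nuclear genes gave 53 and 2. Genes lower and then higher on induction (236) became 533 with DESeq2 and 514 with no filter, and those higher and then lower (61) became 271 and 252. All 357 genes of induced vs uninduced and all 34 of induced vs Control were also called by DESeq2, as were 979 of 985 in uninduced vs Control. The cause of these shifts was not tested. The 4-library fits have fewer libraries to estimate the spread, yet that of induced vs Control gave more calls. It leaves out the uninduced libraries, whose replicates differed most. Their chi-square per degree of freedom was 54.1, against 20.6 in Control and 16.4 in induced libraries.

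Leaving out 1 library at a time let more genes be tested (19233 to 21302) and left an arm of 1 library, which is assumed to vary like the others. Higher and lower genes then ranged from 185 to 1007 and from 260 to 1165 in uninduced vs Control, from 156 to 951 and from 15 to 549 in induced vs uninduced, and from 20 to 266 and from 0 to 71 in induced vs Control. Genes lower and then higher ranged from 137 to 768, and those higher and then lower from 13 to 453. Rbpj ranged from -1.445 to -1.296, from 2.797 to 2.845 and from 1.398 to 1.509 in the 3 comparisons.

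With the replicate number as a block, induced vs uninduced had 133 lower genes, induced vs Control had 101 higher and 7 lower, and 112 genes were higher and then lower. Replicates with the same number deviated with correlations of -0.041, 0.025 and 0.011 across all genes tested. These values show no pairing, but cannot exclude one, because deviations particular to 1 library can hide it.

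With the 4 compared libraries alone, 20 named genes other than Rbpj lost their call in uninduced vs Control and 25 in induced vs uninduced. A change of sign counted as a reversal only where the main fit or the alternative passed, and otherwise as staying. Genes without a value in an alternative were left out of it. Over all alternatives, named genes stayed on their side of the threshold 1781 times, gained a call 137 times, lost one 115 times and never reversed in that sense. Lists did so 366, 19 and 44 times and reversed 3 times: the B-lineage list without uninduced replicate 2 in uninduced vs Control (signed adjusted p -0.735, against 0.000284 with all libraries and 0.000989 without Control replicate 1) and in induced vs uninduced (0.687, against -3.06e-05 and -8.2e-05), and the conventional dendritic list without uninduced replicate 1 in induced vs uninduced (-0.000592, against 0.839 with all libraries, 0.925 without induced replicate 2 and 7.4e-05 without uninduced replicate 2). The 2 uninduced libraries thus gave calls of that list in opposite directions. The sign gives the direction of these camera results.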

Other observations

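The surface marker genes, receptor segments and composition of the 34 genes were examined after the comparisons had been seen. So were the tests of a wrong group label, of a difference between mice or sorts, of sequencing depth, of listed genes standing out in Control replicate 2 and of both explanations of Rbpj-ps3. Genes and gene segments of the T-cell receptor beta locus, Trbc1 and Trbc2 included, were low in uninduced libraries as a group. Of 22 tested, 13 fell, and all 22 had fold changes below 0. Their summed level was 525 and 388 CPM in Control, 8.69 and 8.36 CPM in uninduced and 169 and 187 CPM in induced libraries. In Control, Trbc1 alone stood at 258 and 184 CPM and Trbc2 at 82.7 and 96.8 CPM, so much of that sum repeats these genes. On induction 7 of the 22 rose. Genes and segments of the immunoglobulin heavy chain locus summed to 276 and 190 CPM in Control, 40.7 and 693 CPM in uninduced and 206 and 202 CPM in induced libraries. Most of each sum was the constant gene Ighm. It stood at 264 and 171 CPM in Control, 32.3 and 643.5 CPM in uninduced and 194 and 180 CPM in induced libraries. Among genes of surface proteins, Kit, the stem cell factor receptor, was at 0.21 in uninduced vs Control (adjusted p = 0.742) and Cd24a at 0.52 (adjusted p = 0.452). Cd44 fell by 0.89 on the log2 scale (adjusted p = 0.0188), and Ptprc, which encodes CD45, fell by 1.16 (adjusted p = 0.00956) and rose by 1.04 on induction (adjusted p = 0.029).

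Of the 34 genes higher in induced libraries than in Control, 25 were also higher in uninduced libraries. Independent lists would share 0.846. Simulated sets with no group difference shared 0.4 on average and at most 4, from only 1.4 and 1.55 calls. Across genes the covariance of the log2 fold changes was 0.774 against a simulated 0.657, but their correlation of 0.358 was below the simulated 0.506, and part of the overlap can come from the shared Control libraries. The 25 include Gata2, Mfsd2b, Car1, Samd14, Lmo2, Il1rl1, Ms4a2, Apoe and Tfr2. The other 9 are Rbpj, Rbpj-ps3, St8sia6 and the interferon-inducible genes Oasl2, Ifi44, Ifit1, Ddx60, Iigp1 and Slfn5, chosen for mention after their values were seen.

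A hypothesis from the erythroid and mast cell genes is that uninduced libraries hold more RNA of megakaryocyte and erythroid progenitors. A list of 15 further genes of those cells was written before any of their values had been looked at, but after Gata2, Klf1, Car1 and other such genes had been seen to be higher, so it is not independent of the pattern. Of the 14 that could be tested, 7 rose and none fell in uninduced vs Control in edgeR (9 adjusted over the list alone), and their median log2 fold change was 2.61, between 2.41 and 3.005 without each library in turn. This goes with the hypothesis. In induced vs Control the median log2 fold change of the list was 2.24, with 0 genes called higher in edgeR. The shift was therefore not particular to uninduced libraries. In induced libraries Ermap stood at 63.4 and 48.5 CPM, Car2 at 173 and 147 CPM and Zfpm1 at 129 and 153 CPM. In uninduced libraries Ermap stood at 98.8 and 393 CPM against 0.381 and 4.60 CPM in Control, Car2 at 208 and 609 against 64.95 and 47.8 CPM and Zfpm1 at 118 and 294 against 35.7 and 44.4 CPM. Of the 15, 6 had at least 1 CPM in both Control libraries. The 4 hemoglobin genes, abundant in later red cells, summed to 0.348 and 53.9 CPM in the uninduced libraries beside 33.4 and 94.96 CPM of Klf1, and to 4.87 and 14.9 CPM in Control beside 0.305 and 1.77 CPM. A test of red blood cells that also used 1 more gene is left at these values. A different mix of sorted cells and a change within cells give the same sum in RNA from whole sorted samples, and the labels do not give the markers of the sort.

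B-lineage genes were high in RBPJ uninduced replicate 2 and not in replicate 1. A library of another group under this label is argued against by Rbpj, which lay 1.28 below the lowest Control or induced library on the log2 CPM scale and within 0.09 of replicate 1. For mature B cells, the ratio of summed early B genes (Igll1, Vpreb1, Vpreb2) to mature ones (Ighd, Fcer2a, Ms4a1, Cr2) was 0.175, but the early genes were 15.5 times the highest other library, so mature B cells, and B-lineage cells of several stages, stay open; of the 19 B-lineage genes listed, 4 had at least 1 CPM in both Control libraries. The ratio of summed Y-linked gene CPM to Xist CPM differed 34.8-fold between the 2 libraries, against 2.63-fold in Control and 1.71-fold in induced libraries, so the 2 libraries differed in their mix of male and female RNA. This goes with a difference between mice or sorts but does not tie it to the B-lineage genes, so it stays open, and a biological explanation was not tested. Some dendritic and myeloid list genes, named after their values were seen, were also higher in uninduced replicate 2 than in replicate 1. Cd74 stood at 233 against 13.0 CPM, H2-Aa at 41.2 against 0 CPM, S100a9 at 54.4 against 0 CPM and Ngp at 22.1 against 0 CPM. Other members, such as Mpo (2718 against 3712 CPM) and Sirpa (22.7 against 45.6 CPM), were higher in replicate 1. Of other dendritic list genes, Zbtb46 stood at 27.0 against 7.48 CPM and Itgax at 7.36 against 0.174 CPM. Xcr1 (1.56 against 0 CPM), Clec9a (0.223 against 0 CPM) and Batf3 (0 CPM in both) were near the floor. These values do not show whether dendritic or B-lineage cells gave the RNA of Cd74 and H2-Aa.

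Control replicate 2 had counts in more genes than any other library, 30343 against at most 24025. Depth is argued against by its total of 5311391 counts, below that of every library but uninduced replicate 1 (5098927). At equal depth it had 1.36 times as many genes as the highest other library, a ratio that thinning the deeper libraries could hardly lower. Of 14607 counts in 3682 genes seen only there, the top 100 genes held 11.9%, below the 20% set in advance as a bound against another cell type. That bound was too narrow, because it leaves out cells whose genes are also seen elsewhere: 10 listed genes, 4 of later thymocytes and mature T cells, 5 of the T lineage and 1 natural killer and innate lymphoid gene, had at least 10 CPM there and over 4 times the level of every other library, so another cell type stays open. Reads spread evenly over the genome stay open too: 34.04% of olfactory receptor genes had a count against at most 9.08% elsewhere, a ratio of 3.75, but the correlation of count with exonic length across protein-coding genes seen in no other library was 0.148 (Spearman, across genes, which are not independent replicates), below the 0.2 set in advance for it, and no biological explanation was tested.

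Counts of Rbpj-ps3 rose more than those of Rbpj in the induced libraries. A fixed share of Rbpj reads counted at the pseudogene would keep the ratio of the counts equal, so the pattern itself argues against it. The lowest induced ratio was 6.80 times the highest of the other 4 libraries, which gives the size of the pattern and is no separate test. In the induced libraries the pseudogene's counts were 36.0% of those of Rbpj (median of 2). One possible explanation is RNA of the inducible Rbpj copy that matches the pseudogene better than it matches spliced Rbpj, and it stays open because gene counts hold no read positions or bases.

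Xist was at 497 CPM in uninduced replicate 2 and at 1559 to 2103 CPM in the other libraries. The Y-linked gene Ddx3y was at 8.69 CPM in uninduced replicate 1 and at 15.9 to 62.2 CPM in the others.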
